A study of Aedes aegypti with 4 samples.

How the data were processed

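RNA sequencing measured transcripts of Malpighian tubules from Aedes aegypti in 4 groups with 1 library each: MGYP2.tet, MGYP2, OB and OB-wMel, 2 days after a meal of blood infected with Dirofilaria immitis. Per the labels' protocols, mosquitoes went 12 h without food before blood holding 6 to 12 microfilariae per microlitre was offered, total RNA came from pooled tubules with the PureLink kit, and the libraries were non-directional, so reads of a gene and of an antisense partner cannot be separated. The deposited table gives, per the file headers, total counts of trimmed paired reads for 34403 transcripts; the aligner, the counting rule and the genome build are not given in the sources used here, and coordinates are printed as the table gives them. It also holds RPKM values, which the authors computed per kilobase of transcript and scaled to library size, and values headed CPM, treated as a score because in the deposited table their columns do not sum to the same total and so rest on an adjusted library size. The authors' log fold changes and FDR values for comparisons between single libraries are also in the deposited table. The counts alone entered the comparisons, and the libraries were matched to the groups of the authors' comparisons through the header names and the larger RPKM of each pair, which equalled the listed group mean in 34403 of 34403 transcripts for each of the 4 comparisons.

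Counts were summed over the transcripts of each of 19713 genes. Names come from the table alone, which describes 6105 genes (31.0%); 0 of the 19713 gene identifiers matched the RefSeq table of assembly AaegL5.0, which was therefore not used. The filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15, smallest group 1) kept 10284 genes with 99.9% of the counts, 4390 of them with an informative name. Values are CPM, a gene's counts relative to the library total scaled by the trimmed mean of M values (TMM), and log2 ratios add a prior count of 2. Folds are ratios of these CPM values without the prior count, with an exact conditional binomial 95% interval; a fold against a count of 0 is a lower bound at a floor of 3 counts per library, which corresponds to 0.232 to 0.348 CPM. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

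With 1 library per group the 4 comparisons (MGYP2 with MGYP2.tet, OB-wMel with OB, MGYP2.tet with OB, MGYP2 with OB-wMel) have no test, and genes were counted by a size rule of at least 2-fold. The 1 test these libraries allow is an additive model of background and Wolbachia over all 4, fitted with edgeR's quasi-likelihood method with Benjamini-Hochberg adjustment at 0.05. It has 1 residual degree of freedom, borrows spread across genes (common dispersion 0.113, prior degrees of freedom 5.62), takes the other background as the replicate, and cannot test a difference between backgrounds in the Wolbachia effect. Its p-values measure only the spread between these libraries. The SE given with a log2 value is approximate. It is the size of that value divided by the square root of the F statistic of the test. Correlations and shares of same-sign genes described how far the comparisons moved together, set against crossed pairs, beside the overlap that independent lists of the same sizes would have.

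Gene lists were defined by product names: 28 of functions (antimicrobial peptides; lysozymes; recognition proteins; lectins; fibrinogen-related, melanization and immune signalling proteins; small RNA, antioxidant and iron genes; cytochrome P450s, glutathione transferases, UDP-glycosyltransferases, carboxylesterases and ABC transporters; ion and water transport; purine and ammonia genes; oxidative phosphorylation; cytosolic and mitochondrial ribosomal proteins; proteasome; heat shock; autophagy; apoptosis; lipids; cuticle; odorant binding; cell cycle) and 7 of tissue markers (midgut digestive enzymes, fat body, ovary and eggshell, muscle, salivary gland, haemocytes, nervous system). Each list with at least 3 tested members is described by the percentile of its median log2 ratio among 10000 random lists of the same size matched on mean expression, as a description of these libraries. UDP-glycosyltransferases and the ovary list had 2 tested members each, carboxylesterases and haemocytes 1 each, too few for this. The patterns for the 2 enzyme lists missed genes annotated as glucosyl/glucuronosyl transferases or carboxy/choline esterases, so they do not stand for those families. The digestive enzyme pattern took in TMOF, a hormone, by the word trypsin. The mitochondrial genome list and an oxidative phosphorylation list without mitochondrial-genome and vacuolar members were added after the data were seen.

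Named genes were drawn from a rule, and not every gene it selects is named. They have a mean of at least 10 CPM. For each effect the rule takes the 8 higher and 8 lower with an informative name and the largest smaller log2 ratio of both pairs, at least 2-fold with the same sign in both (5 existed for higher with Wolbachia); for each comparison the 3 highest and 3 lowest with a name and up to 2 unnamed per direction; and for each list the 4 members with the largest mean log2 ratio per effect and the 2 most abundant. Genes outside this rule are said to have been chosen after their values were seen. Among those left out is an item that, with 1 test of its pattern made after it was seen, is not reported here. The design, the lists, this rule and most alternatives were fixed before the data were examined.

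The steps were tested on simulated counts with known folds for 9933 genes. Changed genes were drawn only from those above a floor of expected counts, and no simulated Wolbachia effect differed between backgrounds. The rates below therefore do not cover genes of lower counts or effects that differ between backgrounds. For the Wolbachia effect edgeR recovered 14% of 50 genes changed 2-fold, 76% at 4-fold, 98% at 8-fold and 98% at 32-fold, and for background 10%, 64%, 90% and 98%. It called 21 and 25 of 9733 unchanged genes, so the share of false calls in a short list can exceed the nominal level. Of random lists, 5.42% lay outside the central 95%. Alternatives were DESeq2 1.42.0 size factors and its Wald test, total library size, no filter beyond 1 read, at least 10 CPM in 1 library, prior counts of 0.5 and 10, a 4-fold rule and edgeR's robust option; counts per transcript, leaving out genes with over 80% of their scaled counts in a single library, leaving out the mitochondrial genome, and crossed comparisons were added after the data were seen. Work was done in R 4.3.3 with limma 3.58.1.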

Results

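RNA sequencing was done on Malpighian tubules, the excretory organs of the mosquito, in which larvae of the dog heartworm Dirofilaria immitis develop. The mosquitoes, about 7 days old, had taken blood carrying the parasite 2 days before dissection, and each pool held tissue from more than 10 mosquitoes. The 4 groups cross 2 genetic backgrounds with the presence of wMel, a strain of the intracellular bacterium Wolbachia: MGYP2.tet (MGYP2 background, kept free of wMel with tetracycline), MGYP2 (carrying wMel), OB (a parasite-susceptible strain without wMel) and OB-wMel (wMel brought into the OB background by 8 backcrosses). Each group has 1 library, so no group was replicated. The libraries held 10950233 counts in MGYP2.tet, 11307582 in MGYP2, 11684967 in OB and 9285967 in OB-wMel. Reads were seen for 12438, 11607, 12706 and 12093 genes in the same order, and 10284 genes passed the filter on low counts.

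The most abundant transcript of a protein-coding gene was that of AAEL017334, an unnamed gene on chromosome 3, which took 10.3% of the counts in MGYP2.tet, 8.15% in MGYP2, 11.3% in OB and 12.1% in OB-wMel. Transcripts of tubule physiology were abundant in each library. The 16 kDa proteolipid of the V-type proton ATPase (AAEL000291), part of the pump that energises fluid secretion, lay between 2172 and 9986 CPM, and uricase (AAEL002194), which breaks down urate, between 1934 and 4526 CPM. The antimicrobial peptide gambicin (GAM1, AAEL004522) stood between 4574 and 6937 CPM. Transcripts of the mitochondrial genome made up 17.1% of the MGYP2 library (95% Wilson interval 17.08 to 17.12%), against 5.69% in MGYP2.tet, 5.47% in OB and 5.59% in OB-wMel. The mitochondrial 16S ribosomal RNA (AAEL018689) alone held 1245380 counts in MGYP2 and 385403 in MGYP2.tet. The scaling factors of the 4 libraries were 1.11, 0.764, 1.11 and 1.07. With total library size in place of these factors, the median of all tested genes moved to -0.52 (log2) in MGYP2 over MGYP2.tet. In MGYP2 over OB-wMel it moved from -0.02 to -0.49. List medians below are relative to the median of all genes.

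The comparison of MGYP2 with MGYP2.tet asks how wMel alters expression in the MGYP2 background, which was infected artificially. Single immune effectors were higher in MGYP2, although the antimicrobial peptide and lysozyme lists lay within the central 95% of random lists and the recognition protein and lectin lists were lower. Attacin (ATT, AAEL003389; chromosome 3, 79306086 to 79307136), an inducible antibacterial peptide, was 7.56-fold higher (95% interval 7.39 to 7.73), at 5764 against 762 CPM. A protein of the macroglobulin and complement family (AAEL000087) was 13.2-fold higher, the clip-domain protease CLIPA1 (AAEL002601), from a family that acts in melanization cascades, 5.4-fold higher, defensin A (DEFA, AAEL003841) 5.23-fold higher, and the lysozyme LYSC11 (AAEL003723), which cleaves bacterial cell walls, 3.16-fold higher. Midgut-type digestive proteases were lower in MGYP2: female-specific chymotrypsin (AAEL003060) was 94.0-fold lower (95% interval 75.6 to 118), and late trypsin 1 (LT1, AAEL013284; named after its values were seen) 50.8-fold lower. Chitin synthase (AAEL005618), which makes the chitin of the gut lining and cuticle, was 9.53-fold lower, and the chitinase AAEL003066 5.67-fold lower. The peptidyl-prolyl isomerase AAEL011758, of an enzyme class that helps proteins fold, had 7932 counts in MGYP2.tet and 0 in MGYP2, which is at least 1882-fold lower against a floor of 3 counts per library. The serine endopeptidase AAEL002360 likewise had 4595 counts in MGYP2.tet and 0 in MGYP2, at least 1090.0-fold lower.

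Among the gene lists, the 15 tested genes of the mitochondrial genome had a median log2 ratio of 2.40 in MGYP2 over MGYP2.tet, above all 10000 random lists of matched expression, and all 15 were at least 2-fold higher. Cytochrome c oxidase subunits COX2 (AAEL018664) and COX3 (AAEL018669), which pass electrons to oxygen, were 8.0-fold and 4.08-fold higher. The 87 cytosolic ribosomal protein genes had a median of 1.05, also above all 10000 random lists. RpL4 (AAEL009994) was 2.14-fold higher. Oxidative phosphorylation, the list fixed as nuclear-encoded, had a median of 0.79 (percentile 99.98). It took in 3 genes of the mitochondrial genome and also vacuolar ATPase subunits, and 16 of its 28 tested members remain without both. Heat shock proteins and chaperones stood at 0.49 (percentile 99.90), and heat shock cognate 70 (AAEL019403), a constitutive chaperone, was 2.66-fold higher. That median is positive only against the shift of all genes, since it would be near 0 on total library size. On the lower side were digestive enzymes at -1.56 (below all 10000 random lists), or -1.25 with members at 0 counts set to their bound, cuticle and chitin proteins at -1.16 (percentile 0.08), or -0.88 on such bounds, and muscle genes at -0.58 (percentile 0.04). In all, 826 genes were at least 2-fold higher and 1360 at least 2-fold lower in MGYP2. With total library size the split was 387 higher and 2653 lower.

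The comparison of OB-wMel with OB asks the same in the parasite-susceptible background. Digestive proteases were again lower with wMel. Trypsin 3A1 (AAEL007818) was 336-fold lower (95% interval 219.7 to 543) and female-specific chymotrypsin 13.1-fold lower. Trypsin 3A1 had 9186 counts in OB, 21 in OB-wMel, 103 in MGYP2.tet and 17 in MGYP2. It thus stood far below OB in MGYP2.tet too, which has no wMel. Outside the digestive list, the metalloproteinase AAEL014516 was 2473-fold lower (95% interval 444 to 97700.0), with 3219 counts in OB, 1 in OB-wMel, 3 in MGYP2.tet and 0 in MGYP2. Stress-inducible chaperones were lower too: HSP70Bb (AAEL017976) was 26.1-fold lower and a 26 kDa heat shock protein (AAEL013350) 29.5-fold lower. Of the proton pump, the catalytic subunit VhaA (AAEL008787) was 2.09-fold lower and the 16 kDa proteolipid 1.96-fold lower; the latter was 2.23-fold higher in MGYP2. Vitellogenin-A1 (AAEL010434), the main yolk precursor, was 9.04-fold higher and vitellogenic carboxypeptidase (Vcp, AAEL006563) 9.88-fold higher, while Vcp was 2.84-fold lower in MGYP2. Cathepsin b (AAEL009642), a lysosomal protease, was 10.1-fold higher, and the prophenoloxidase PPO5 (AAEL013492), which oxidises phenols to melanin, 5.73-fold higher. Attacin was 2.72-fold lower, opposite to its direction in MGYP2.

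Digestive enzymes had a median of -1.30 (below all 10000 random lists) in OB-wMel over OB, or -1.13 with members at 0 counts set to their bound, heat shock proteins and chaperones -0.52 (below all 10000 random lists), ion and water transport genes -0.76 (below all 10000 random lists), and melanization proteins 0.42 (above all 10000 random lists). The heat shock list also stood apart between backgrounds, at -0.47 (below all 10000 random lists) in MGYP2.tet over OB and 1.22 (above all 10000 random lists) in MGYP2 over OB-wMel. The oxidative phosphorylation list had a median of -0.45 (below all 10000 random lists), the genes of the mitochondrial genome -0.16 (percentile 2.38) and cytosolic ribosomal proteins 0.07 (percentile 87.6). In all, 336 genes were at least 2-fold higher and 717 at least 2-fold lower in OB-wMel. The split was 665 and 1131 with no filter, and 100 and 258 when at least 10 CPM was asked for in 1 library. With a prior count of 10 it was 163 and 433. The vitelline membrane protein 15a-1 (AAEL013027) had 1356 counts in OB and 3, 0 and 9 in MGYP2.tet, MGYP2 and OB-wMel, and oskar (AAEL000442; named after its values were seen), which assembles germ plasm, had 159 against 6, 0 and 2.

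Set side by side, the Wolbachia comparisons were weakly related across all genes, while digestive enzymes were mostly lower in both. Of the 55 genes tested in that list, which includes the hormone TMOF by its name, 24 were at least 2-fold lower with wMel in both backgrounds and 1 at least 2-fold higher in both. The exception, the putative trypsin AAEL006121, was 2.48-fold and 2.38-fold higher. The most abundant member, trypsin-alpha (AAEL008079), differed little, at 1.18-fold lower in MGYP2 and 1.39-fold lower in OB-wMel. The odorant-binding protein OBP22 (AAEL005772), of a family that carries small hydrophobic molecules, was 2.91-fold and 3.21-fold higher. The aquaporin AAEL005008, a water channel, was 2.08-fold and 2.51-fold lower. Across the 10284 genes, Pearson's r between the log2 ratios was 0.145 and Spearman's rho 0.0111, genes not being independent replicates. The pairs share no library. Of 517 genes at least 2-fold apart in both, 66.0% had the same sign: 56 were higher in both (27.0 for independent lists) and 285 lower in both (94.8), while 96 (57.6) and 80 (44.4) went opposite ways. Without the digestive enzymes r was 0.124.

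**Figure D1:**
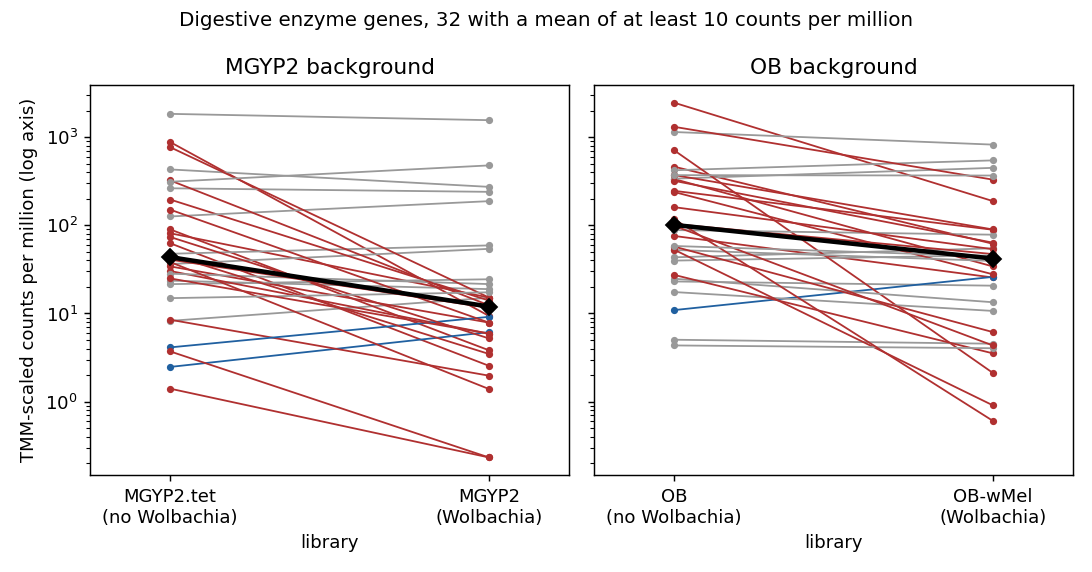
TMM-scaled CPM (log axis) of the 32 genes of the digestive enzyme list (hormone TMOF included) with a mean of at least 10 CPM, each line joining a gene's value without and with Wolbachia in the MGYP2 (left) and OB (right) backgrounds; red lines are genes at least 2-fold lower with Wolbachia, blue at least 2-fold higher, grey within 2-fold, and black diamonds mark the median. Most lines slope down in both panels, and the most abundant gene, trypsin-alpha, stays near its level.

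The additive model, with the backgrounds standing in for replicates of the Wolbachia effect, tested which genes moved alike in both. The pairs are not like replicates. Tetracycline in MGYP2.tet and the backcrosses behind OB-wMel go along with wMel status, and these libraries cannot separate them from it. Actin-related protein 2/3 complex subunit 3 (AAEL027716; chromosome 3, 109925538 to 109926479), part of the complex that nucleates branched actin, rose with wMel: 12.7-fold higher in MGYP2 and 10.2-fold higher in OB-wMel (log2 3.47, SE 0.36; adjusted p = 0.0221, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its counts were low, from 9 in MGYP2.tet to 321 in OB-wMel. The unnamed gene AAEL027748 had 0 counts in both libraries without wMel and rose, at least 52.0-fold and at least 73.3-fold higher (edgeR adjusted p = 0.0193; named after its values were seen). The third gene that rose, the unnamed AAEL026177, had 14 counts in MGYP2.tet, 537 in MGYP2 and 0 in both OB libraries (edgeR adjusted p = 0.0339), so its call rests on the MGYP2 background alone. In the digestive enzyme list 5 genes fell, and 1 of these, TMOF, is not an enzyme. The juvenile hormone-regulated chymotrypsin JHA15 (AAEL001703; chromosome 2, 87887477 to 87888435) was 24.6-fold and 9.82-fold lower (log2 -3.89, SE 0.46; edgeR adjusted p = 0.0339). The trypsin AAEL013623 was 14.2-fold and 9.34-fold lower (edgeR adjusted p = 0.0193). The others were the trypsin AAEL013703, the larval chymotrypsin-like AAEL022646 (named after its values were seen) and TMOF (AAEL017403), a peptide hormone that stops trypsin synthesis, at 195-fold lower in OB-wMel and 12.1-fold lower (95% interval 1.90 to 506) in MGYP2, where it had 1 count. AAEL013703 and TMOF had over 80% of their scaled counts in OB. The serine endopeptidase AAEL001690, outside that list by its name, also fell, 18.9-fold and 12.7-fold lower (edgeR adjusted p = 0.0289). Female-specific chymotrypsin did not pass (log2 -5.10, SE 0.89; edgeR adjusted p = 0.132), but did so by DESeq2, on total library size and with no filter.

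In all, 26 of 10284 genes passed that test for Wolbachia, 3 that rose and 23 that fell, and 539 had an unadjusted p under 0.05. The split was 0 higher and 9 lower when at least 10 CPM was asked for in 1 library, so no gene that rose kept its call, and 22 higher and 130 lower with no filter. At 10 CPM JHA15, AAEL001690, AAEL013703 and TMOF also lost their calls, and JHA15 did so too without the genes over 80% in a single library. Of the 26, 24 were at least 2-fold apart with the same sign in both backgrounds, by log2 ratios with the prior count. Some of these lie at the floor in MGYP2. Among them, 15a-1 and AAEL014516 each had 3 counts in MGYP2.tet and 0 in MGYP2, so that pair shows no measurable difference for them. The OB library decided many of the 26: 18 had their highest level there, and 13 had over 80% of their scaled counts in a single library, 11 of these in OB. Without genes of that kind 12 passed. On simulated counts this test called 21 of 9733 unchanged genes, so the share of false calls among the 26 may exceed the nominal level. DESeq2 called 5 higher and 67 lower, 23 of them shared with edgeR. With counts kept per transcript, edgeR called 0 of 16273 transcripts (484 at an unadjusted p under 0.05), and DESeq2 81. In the digestive enzyme list, with TMOF, 5 genes passed over all genes and 25 adjusted over the list alone. Among heat shock proteins 1 passed both ways, the small heat shock protein l2efl (AAEL013338; named after its values were seen), with 384 counts in OB and 4, 0 and 6 in MGYP2.tet, MGYP2 and OB-wMel. Of the ovary and eggshell list, too small for a percentile, 15a-1 passed (edgeR adjusted p = 0.0172), 1 of the genes with most of their counts in OB. No member of the other 31 lists with at least 3 tested members (33 such lists in all, with the reduced oxidative phosphorylation list) passed by edgeR over all genes. Of their 658 genes 44 had an unadjusted p under 0.05 and DESeq2 called 3. Adjusted over the list alone, cuticle and chitin proteins had 3 calls, fat body proteins 2, and lectins, cytochrome P450s and odorant-binding proteins 1 each.

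**Figure D2:**
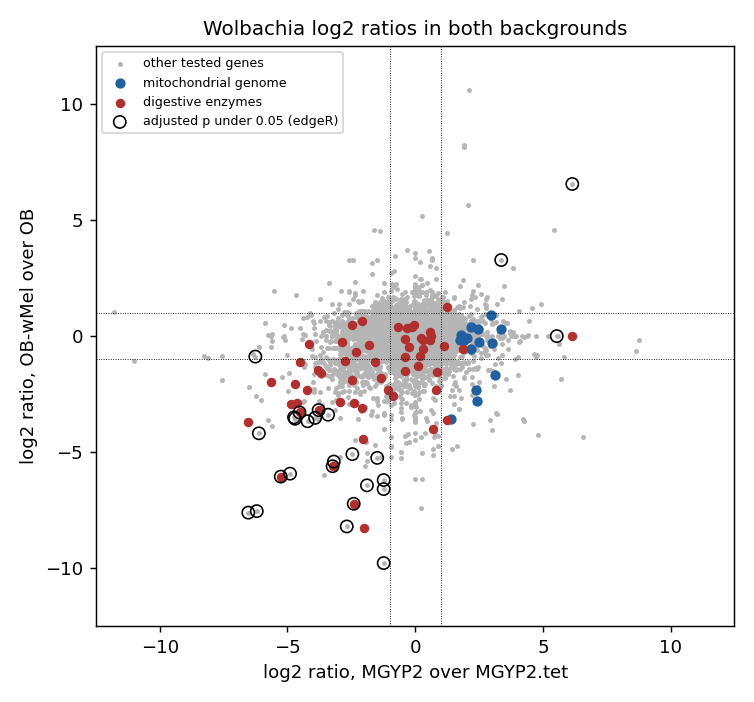
Log2 ratio of MGYP2 over MGYP2.tet (horizontal) against that of OB-wMel over OB (vertical) for the 10284 tested genes, with digestive enzymes in red, genes of the mitochondrial genome in blue, the 26 genes that passed the edgeR test circled, and dotted lines at 2-fold. Of the digestive enzyme list (TMOF included) 24 genes lie in the lower left beyond 2-fold, and the mitochondrial genes lie to the right, from -3.56 to 0.93 on the vertical axis.

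The comparison of MGYP2.tet with OB asks which transcripts differ between the backgrounds without wMel, and that of MGYP2 with OB-wMel asks it with wMel present. Detoxification enzymes differed in either direction: 12 cytochrome P450s were at least 2-fold higher in both pairs and 12 lower, and 7 and 4 glutathione transferases. Of those higher, CYP9J24 (AAEL014613), of a subfamily with members that metabolise pyrethroid insecticides, was 68.5-fold higher in MGYP2.tet and 954-fold higher (95% interval 171 to 37710.0) in MGYP2, with 1 count in OB-wMel. CYP9J22 (AAEL014619) was 13.5-fold and 11.3-fold higher, and CYP9J26 (AAEL014609), the most abundant of the 3, 6.40-fold and 4.49-fold higher. The glutathione transferase GSTD4 (AAEL001054), which conjugates glutathione to toxic compounds, had 0 counts in both OB libraries and was at least 190.2-fold and at least 534-fold higher. An alcohol dehydrogenase (AAEL012457) was 24.9-fold and 154-fold higher. Of immune genes, defensin D (DEFD, AAEL003857) was 11.3-fold and 11.6-fold higher, while the C-type lectin CTL18 (AAEL005482), of a family that binds sugars on microbes, was 70.2-fold lower in MGYP2.tet and 240.2-fold lower (95% interval 66.2 to 1989) in MGYP2. Attacin was 1.16-fold lower in MGYP2.tet but 17.7-fold higher in MGYP2, and LYSC11 8.53-fold higher in MGYP2. Cytochrome b561 (AAEL012832), a membrane electron carrier, was 37.7-fold and 41.8-fold lower.

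The copy AAEL025362 of the ribosomal protein gene RpL10 was 744-fold higher in MGYP2.tet and 339-fold higher in MGYP2. Reads could be split between near-identical copies, so the values of a single copy are uncertain; summed, the RpL10 copies had log2 ratios of -0.51 without and 0.54 with wMel. Without wMel, 1024 genes were at least 2-fold higher and 1143 lower in MGYP2.tet than in OB; with it, 1401 were higher and 1831 lower in MGYP2 than in OB-wMel. On total library size the split for the pair with wMel was 841 higher and 2982 lower. Pearson's r between these log2 ratios across genes was 0.547 and Spearman's rho 0.440, and 89.6% of 1417 genes at least 2-fold apart in both had the same sign, 597 higher and 673 lower (139.5 and 203.5 for independent lists). For the crossed comparisons, MGYP2 over OB and OB-wMel over MGYP2.tet, r was -0.440 and 20.1% had the same sign.

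In the additive model, 402 genes passed for background (edgeR, adjusted as above), 211 higher and 191 lower in the MGYP2 background, and 392 were at least 2-fold apart with the same sign both without and with wMel. GSTD4 passed, higher in both pairs, with an edgeR adjusted p of 0.00300. DEFD was higher by a log2 of 3.52 (SE 0.30; edgeR adjusted p = 0.00398), higher in both pairs. The ATP-binding cassette transporter AAEL010379, an export pump of the cell membrane, was 5.14-fold and 5.16-fold higher (log2 2.36, SE 0.38; edgeR adjusted p = 0.0250). The caspase CASPS8 (AAEL014348), of the proteases of cell death, was 3.01-fold and 3.01-fold higher (edgeR adjusted p = 0.0389), a call lost on total library size, as that of GSTD4 was by DESeq2. The serpin SRPN6 (AAEL010769), a protease inhibitor, did not pass (log2 1.86, SE 0.50; edgeR adjusted p = 0.111; 3.23-fold and 4.11-fold higher). Unadjusted, 1818 genes had a p under 0.05. DESeq2 called 248 higher and 223 lower, 324 shared with edgeR. Over 80% of the scaled counts lay in a single library for 36 of the 402, and 373 passed without such genes. Kept per transcript, edgeR called 0 (1564 at an unadjusted p under 0.05) and DESeq2 523. On total library size the split of calls was 228 higher and 325 lower. It was 414 and 430 with no filter, and 98 and 109 when at least 10 CPM was asked for in 1 library.

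Of lists with background calls by edgeR over all genes, cytochrome P450s had 9 higher and 3 lower in the MGYP2 background, 21 in total when adjusted over the list alone. The digestive enzyme list had 3 higher and 9 lower, TMOF among the latter (18 adjusted over the list alone), melanization proteins 5 and 4 (13), lectins 3 and 3 (7), and glutathione transferases 4 and 2 (9). Lipid metabolism had 2 (2 adjusted over the list alone), both lower, 1 of them the fatty acyl-CoA reductase AAEL013648, at 3.72-fold and 4.88-fold lower. Ribosomal proteins had 2 (2 adjusted over the list alone), 1 higher, the RpL10 copy AAEL025362 named above, and 1 lower. A single call each was made in antimicrobial peptides (DEFD; 2 adjusted over the list alone), ABC transporters (AAEL010379; 3), apoptosis (CASPS8; 1), antioxidant enzymes (2), fibrinogen-related proteins (2), fat body proteins (3), autophagy and lysosome (1), cuticle and chitin proteins (1), odorant-binding proteins (1), heat shock proteins (1) and oxidative phosphorylation (1). The call in the oxidative phosphorylation list was a vacuolar member. The list without mitochondrial-genome and vacuolar members had 0 calls, and so had the mitochondrial genome list. In the ovary and eggshell list, below 3 tested members, 15a-1 (edgeR adjusted p = 0.00300) and oskar (edgeR adjusted p = 0.0292) were lower. Both calls rest on the OB library alone. It held 1356 and 159 counts, against 9 and 2 in OB-wMel of the same background. The heat shock call, l2efl, rests on it too, with 384 counts in OB and 6 in OB-wMel. So do TMOF (1520 and 6) and the trypsin AAEL013703 (684 and 9) among the digestive calls. These calls therefore do not show a difference held by both OB libraries. The other 15 lists with at least 3 tested members had no call by edgeR. Of their 197 genes 17 had an unadjusted p under 0.05 and DESeq2 called 3; adjusted over the list alone, recognition proteins had 1.

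Among immune lists, antimicrobial peptides had a median of 0.53 (percentile 92.4) in MGYP2 over MGYP2.tet and 0.02 (percentile 55.4) in OB-wMel over OB, against 2.06 (above all 10000 random lists) in MGYP2 over OB-wMel. Lysozymes had 0.50 (percentile 85.3), -0.31 (percentile 7.88) and 1.60 (percentile 99.4) in the same comparisons. Recognition proteins were at -1.19 (percentile 0.41) with Wolbachia in MGYP2, where PGRPLA (AAEL012380), which binds peptidoglycan, was 4.23-fold lower and PGRPS1 (AAEL009474) 3.72-fold higher, and at -0.14 (percentile 21.8) in OB. C-type lectins and galectins had -0.47 (percentile 1.02) and -0.19 (percentile 3.46). Galectin GALE8A (AAEL005293), a sugar-binding protein, was 4.92-fold and 1.75-fold lower. Fibrinogen-related proteins had -0.39 (percentile 10.3) and -0.28 (percentile 4.07), or -0.25 and 0.00 with members at 0 counts set to their bound, and Toll, IMD and JAK-STAT signalling -0.39 (percentile 1.78) and 0.06 (percentile 79.8). REL1A (AAEL007696), the transcription factor of the Toll pathway, was 1.89-fold lower and 1.12-fold higher. Melanization proteins were at 0.28 (percentile 99.89) in MGYP2, and at -0.34 (below all 10000 random lists) in MGYP2.tet over OB and -0.48 (percentile 0.11) in MGYP2 over OB-wMel. Small RNA pathway genes had 0.08 (percentile 57.3) and 0.14 (percentile 90.4), with dicer-2 (AAEL006794), which makes antiviral small RNAs, 1.05-fold and 1.35-fold lower. On total library size without recentring, the positive medians in MGYP2 over MGYP2.tet of antimicrobial peptides, lysozymes, melanization and small RNA genes would be near or below 0.

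Of detoxification and excretion lists, cytochrome P450s had medians of 0.03 (percentile 66.9) in MGYP2 over MGYP2.tet, -0.12 (percentile 0.66) in OB-wMel over OB and 0.41 (percentile 99.98) in MGYP2 over OB-wMel. CYP6BY1 (AAEL017539) was 4.33-fold and 1.84-fold higher with wMel. Glutathione transferases had 0.29 (percentile 95.8) and 0.16 (percentile 98.3) with Wolbachia, and ABC transporters -0.47 (percentile 0.33) and 0.11 (percentile 93.7). Ion and water transport genes were at -0.09 (percentile 17.9) in MGYP2, and purine and ammonia genes at -0.09 (percentile 23.4) and 0.05 (percentile 65.2). Glutamine synthetase AAEL013458, which fixes ammonia, was 2.87-fold and 1.59-fold lower, and uricase 1.36-fold and 1.63-fold lower. Antioxidant enzymes had 0.46 (percentile 97.47) and -0.32 (percentile 0.08), with thioredoxin reductase (AAEL002886), which keeps thioredoxin reduced, 2.29-fold higher and 1.33-fold lower. Iron-binding proteins had -0.42 (percentile 4.53) and 0.19 (percentile 91.9). A ferritin subunit (AAEL007385), which stores iron, was 1.76-fold lower and 1.17-fold higher. On total library size without recentring, the positive medians in MGYP2 over MGYP2.tet of the P450, glutathione transferase and antioxidant lists would be negative. The P450 median in MGYP2 over OB-wMel would be near or below 0, since the median of all genes there was -0.49 on that scale.

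Proteasome subunits, which degrade tagged proteins, had medians of 0.40 (percentile 99.74) in MGYP2 and 0.15 (percentile 99.71) in OB-wMel, and mitochondrial ribosomal proteins 0.28 (percentile 91.5) and -0.31 (percentile 0.40). Autophagy and lysosome genes had -0.09 (percentile 14.96) and 0.14 (percentile 98.95), apoptosis genes -0.08 (percentile 33.6) and -0.07 (percentile 23.8), and lipid metabolism -0.10 (percentile 22.8) and 0.23 (percentile 98.5). Cathepsin l (AAEL002833), a lysosomal protease, was 2.54-fold lower and 1.03-fold higher. Odorant-binding proteins had -0.69 (percentile 3.97) and 0.29 (percentile 96.1), cell cycle genes -0.27 (percentile 12.7) and -0.21 (percentile 2.67), and cuticle and chitin proteins 0.00 (percentile 58.0) in OB-wMel. On total library size without recentring, the medians of proteasome subunits and mitochondrial ribosomal proteins in MGYP2 would be negative. Oxidative phosphorylation without its mitochondrial-genome and vacuolar members, a list made after the data were seen, had 0.68 (percentile 99.81) and -0.41 (below all 10000 random lists). Of tissue markers, fat body proteins had -0.14 (percentile 28.3) and 0.04 (percentile 62.1) with Wolbachia and -0.85 (percentile 0.16) in MGYP2.tet over OB, or -0.33 before centring with the member at 0 counts set to its bound, where apolipophorin-III (AAEL008789), a lipid carrier of the haemolymph, was 1.83-fold lower. Muscle genes had 0.02 (percentile 56.8) in OB-wMel, with troponin C (AAEL000744), the calcium switch of contraction, 2.27-fold lower in MGYP2. Salivary gland markers had 0.17 (percentile 80.8) and -0.08 (percentile 31.8), and nervous system markers -0.50 (percentile 12.7) and -0.28 (percentile 13.1). Of lists too small for a percentile, the UDP-glucuronosyltransferase AAEL005903, which adds sugars to toxic compounds, was 7.02-fold lower in MGYP2 and 1.66-fold lower in OB-wMel, and the carboxylesterase AAEL003545 2.15-fold lower and 1.58-fold higher. Less abundant members, added after their values were seen, were the UDP-glucuronosyltransferase AAEL008749 (log2 0.58 and 1.34) and the haemocyte marker lozenge (AAEL007040; log2 -1.18 and -1.63, at 13 counts or fewer). The ovary members are 15a-1 and oskar above. Of the 32 lists 13, 13, 10 and 13 lay outside the central 95% of random lists in MGYP2 over MGYP2.tet, OB-wMel over OB, MGYP2.tet over OB and MGYP2 over OB-wMel. Lists of genes drawn at random would give 1.6. That number does not allow for genes of a list that vary together, so it tests no effect of wMel or background.

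**Figure D3:**
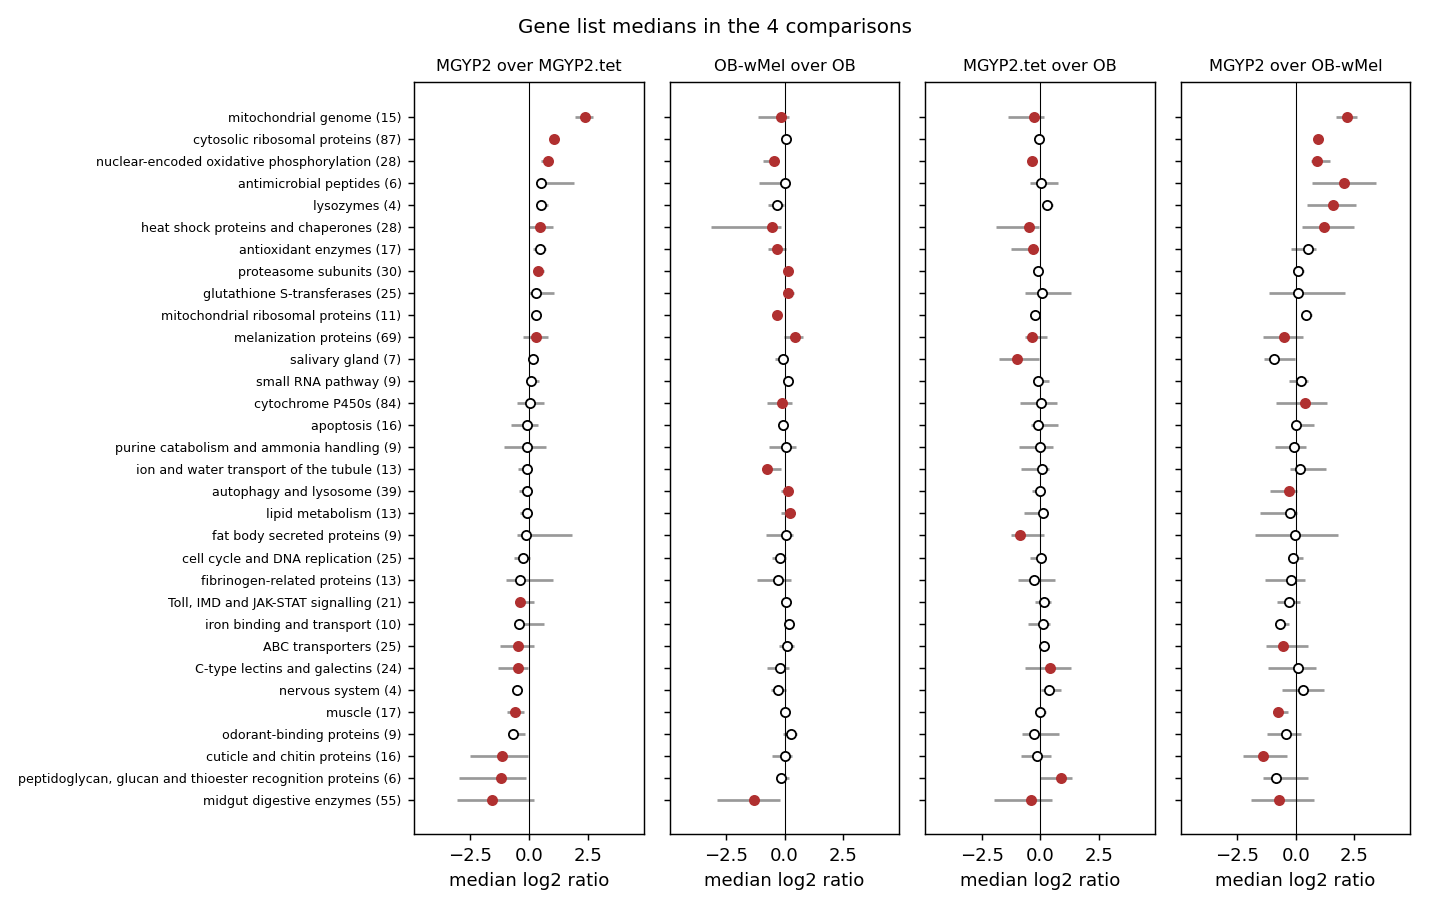
Median log2 ratio (horizontal) of 32 gene lists, with the number of tested members in brackets, in the 4 comparisons; bars span the quartiles and filled circles lie outside the central 95% of 10000 random lists matched on expression. Mitochondrial genome and ribosomal protein lists stand to the right wherever the MGYP2 library is compared, and digestive enzymes to the left in each panel.

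The authors' own comparisons in the deposited table, made per transcript between single libraries, list an FDR under 0.05 for 5076 transcripts between MGYP2.tet and MGYP2, 2760 between OB and OB-wMel, 5103 between OB and MGYP2.tet and 6068 between MGYP2 and OB-wMel. They gave a value for 23575 of 34403 transcripts. Such tests on the reads of 2 libraries compare those libraries and not the conditions, and they were not used here for calls.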

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

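The tests of mitochondrial reads as a cause of the ribosomal pattern and of neighbouring genes with opposite calls were planned, and the tests of transcript length, of a shared Wolbachia effect, of carried-over midgut and of single dissections were chosen only after the result was seen. A first look at carried-over midgut on a pair of genes was replaced by the test on the 31 enzymes of the list with a mean of at least 10 CPM. Differences between the backgrounds in the Wolbachia effect were not tested in any case below, because with 1 library per group the additive model cannot test them.

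Genes of the mitochondrial genome differed between backgrounds by 2.56 (median log2 difference with Wolbachia in MGYP2 minus that in OB), and the MGYP2 library also held higher cytosolic ribosomal protein transcripts. The tables argue against transcript length as the whole cause of either: with the length trend removed the medians in MGYP2 over MGYP2.tet were 2.24 for mitochondrial genes (2.40 before) and 1.0001 for ribosomal proteins (1.05 before). Leaving mitochondrial genes out before scaling kept the ribosomal median at 1.05, which decides nothing, because reads they take up lower all other genes alike. A Wolbachia effect shared by both backgrounds would have raised mitochondrial genes in OB-wMel, where the median over OB was -0.16. A Wolbachia effect in the MGYP2 background alone, a difference in RNA quality or enrichment, and a difference between single pools may each be the cause, and stay open as untested.

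Digestive enzymes were lower in both Wolbachia libraries, 24 genes of that list (the hormone TMOF included) at least 2-fold in both, although 14 of the 55 stood above 10 CPM in every library, none is held by another list, and trypsin-alpha stayed between 825 and 1842 CPM. If the tubule pools without wMel carried more midgut of the same makeup, 1 remaining share should describe the list: in the MGYP2 pair 35.5% of 31 genes (11; TMOF left out) lay outside the best share, and in the OB pair 58.1% (18; 14 above and 4 below a remaining share of 10.7%). The MGYP2 value decides little, because the level taken off as the tubule's own was mostly that of the MGYP2 library itself. With 1 library per group, a difference in dissection between pools cannot be told apart from an effect of wMel, since no replicate shows how far such pools differ. Pools of the same wMel status but different background differed for this list too. The median was -0.38 in MGYP2.tet over OB, with 10 genes at least 2-fold higher and 20 lower. It was -0.70 in MGYP2 over OB-wMel, with 11 higher and 24 lower. The Wolbachia pairs had 5 higher and 30 lower in MGYP2, and 1 and 31 in OB. Background differs between the former pools, so their values do not measure dissection alone. Lower digestive enzyme transcripts under wMel, in the tubule or in tissue carried over with it, are a candidate explanation that stays open.

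Some background calls came as neighbours with opposite directions. Reads shared between neighbouring copies as a general cause of the 402 calls are argued against: 61 had a call of the opposite direction among the 5 nearest tested genes on either side, against a median of 69 (95th percentile 86) in 1000 reshuffles. A real difference in gene copies between the backgrounds stays open, as untested.

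Genes of the oxidative phosphorylation list, which includes 3 mitochondrial-genome members and also vacuolar members, were higher with Wolbachia in MGYP2 and lower in OB. The difference of 1.24 between the medians was not tested. Without mitochondrial-genome and vacuolar members the difference of that list was 1.09. Heat shock proteins and chaperones were likewise higher in MGYP2 and lower in OB, by 1.01; on total library size without centring the MGYP2 median would be near 0. The peptidyl-prolyl isomerase AAEL011758 was lower with Wolbachia in MGYP2, where it had 0 counts, and higher in OB, a difference of -12.82 that depends on the prior count. Vitellogenic carboxypeptidase (Vcp, AAEL006563) was lower in MGYP2 and higher in OB, a difference of -4.80.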

How the results depend on the processing

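Counts per transcript, genes with over 80% of their scaled counts in a single library, the mitochondrial genome left out and the crossed pairs were tests chosen only after the result was seen. Requiring at least 10 CPM in 1 library, which tests fewer genes, gave 1009 genes at least 2-fold apart with Wolbachia in MGYP2, 358 in OB, 877 between backgrounds without wMel and 1566 with it. A 4-fold rule, stricter by construction, gave 731, 308, 868 and 1229. With no filter, which tests more genes, 1796 were at least 2-fold apart in OB, and with a prior count of 10, which shrinks ratios of low counts, 596. The correlation of the Wolbachia comparisons was 0.113 with no filter and 0.210 at 10 CPM (the cause was not tested).

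The edgeR test of Wolbachia called 93 genes on total library size, 152 with no filter and 9 at 10 CPM, DESeq2 called 72 (the cause was not tested), and 12 passed without the genes over 80% in a single library. Background calls were 844 with no filter (more genes tested) and 207 at 10 CPM (fewer). Per transcript edgeR called 0 for either effect, with a common dispersion of 0.369 against 0.113 per gene, while 484 and 1564 transcripts had an unadjusted p under 0.05 and DESeq2 called 81 and 523. The other alternatives run left each of these counts within 1.5 times, with total library size changing the splits given in the report. Gene lists outside the central 95% numbered 49 of 128 list comparisons, 50 with DESeq2 size factors and 48 on total library size, and 47 at 10 CPM, which leaves fewer list comparisons. The counts under other scaling factors were nearly fixed in advance, because list medians are centred on the median of all genes.

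No direction of a called value reversed, with list medians centred on the median of all genes. Of the list medians under alternatives 376 stayed within the quartiles and 4 did not, each at the 10 CPM filter. Because of that centring, a change of scaling factors could hardly move them. The 128 medians kept with DESeq2 size factors and the 128 kept on total library size therefore decide nothing. Named genes kept their call, or their lack of one, in 940 cases for Wolbachia, gained a call in 22 and lost one in 6. For background these were 918, 41 and 9. Most of the Wolbachia cases are genes with no call in the main fit, so the 940 does not measure how stable the calls are. Of the Wolbachia losses, 5 came at the 10 CPM filter. Setting members at 0 counts to their bound moved 8 of 132 list medians by more than 0.1, by at most 0.55, and 1 changed sign.

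Leaving out each library in turn leaves 3 libraries and no residual degree of freedom, so the model could not be fitted with a test, and the pair of libraries that remains gives the comparison already in the report. No paired analysis was possible because each group has a single library, beyond the additive model itself, which pairs the libraries by background. Depth limits genes at 0 counts to a floor of 0.232 to 0.348 CPM.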

Other observations

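The test of neighbours in the same direction was run only after the result was seen. Of the 402 background calls, 131 had a call of the same direction among the 5 nearest tested genes on either side, where 1000 reshuffles gave a median of 68 and at most 100. No cause of this was tested.

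Unnamed genes made up many of the large differences. AAEL021694 had 4543 counts in MGYP2.tet, 1799 in MGYP2 and 0 in both OB libraries, and AAEL021585 had 326 in OB, 262 in OB-wMel and 0 in both libraries of the MGYP2 background. AAEL020997 had 5 counts in OB and 7015, 21405 and 8820 in MGYP2.tet, MGYP2 and OB-wMel. AAEL027243 followed it, with 17 in OB and 3722, 9920 and 4537 in the others.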
